A study of Mus musculus with 4 samples.

How the data were processed

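RNA was measured by sequencing in mouse embryonic stem cells of the C57BL/6 strain at passages 25 to 30, grown without feeders on gelatin in LIF and serum, per the labels' protocols. Cells had been transfected with FLAG-tagged mutant Dis3l2 or mock transfected. Dis3l2 is a 3′ to 5′ exoribonuclease that prefers uridylated RNA. The labels call the protein mutant and do not name the mutation. From each condition 1 library was made from input RNA after RiboMinus selection, which removes ribosomal RNA, and 1 from RNA recovered on anti-FLAG M2 affinity gel (RNA immunoprecipitation, IP). RNA was extracted with Trizol and libraries followed Illumina's protocol for low sample amounts, per the labels' protocols.

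Reads were aligned with Bowtie to the mouse build mm9, per the submitters' processing notes. The aligner's version, the counting tool, the use of strand and the treatment of reads with several alignments are not given in the sources used here. The authors deposited 2 tables with 1 column per library. The mRNA table has 16470 RefSeq transcripts, some of them noncoding, and the noncoding table has 6311 Ensembl transcripts, per the file headers and identifiers. The deposited unit is a signal: in both tables, 100% of the values were whole numbers of reads, within 0.02 reads, divided by 1.8 for the mutant input, 2.5 for the mock input, 2.7 for the mutant IP and 2.5 for the mock IP. What these factors stand for is not given in the sources used here. The values were not divided by transcript length. Values were used as deposited, and a difference in scaling between libraries was examined through the alternatives named below. Before the data were examined a length- or depth-normalised unit had been assumed; the same ratios were kept, with no further scaling to a common total.

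In the mRNA table, 26 gene names had been turned into dates and all 26 were restored through their RefSeq accessions. Symbols of 15359 rows of the mRNA table and 3317 rows of the noncoding table were found in a RefSeq gene table of assembly GRCm38, which was used for names and classes only. Clone-based names were left as the files give them. For symbols with several transcripts, the transcript with the highest mean over the 4 libraries stood for the gene. Copies of multicopy RNAs with names of their own were kept apart. Their counts are close but not identical, and whether the reads were divided among copies or counted at each is not given in the sources used here, so copies are not independent observations. RNase P, RNase MRP and some other noncoding RNAs are listed in both tables.

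For each feature log2 ratios were taken with a pseudocount of 1 on the deposited values, among features with at least 1 in any library the ratio used. Such ratios understate the change of low features. The 5 ratios were mutant IP over mock IP, IP over input in each condition, mutant input over mock input, and the specific IP enrichment, which is IP over input in the mutant divided by IP over input in the mock. Features at least 4-fold apart were counted, or at least 2-fold apart between the inputs. With 1 library per group there are no replicates, so no p-value, standard error or count of significant genes is given, and no difference below has a replicate check. For ratios of 2 libraries, exact conditional binomial 95% intervals were computed from the recovered reads. They compare libraries, not conditions, and cover counting error only, since PCR copies are not independent molecules. Where 1 library had 0 reads and the other more than 3, the fold is a bound against a floor of 3 reads per library, which is worth 1.67 in the mutant input, 1.2 in the mock input, 1.11 in the mutant IP and 1.2 in the mock IP.

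The 34 gene lists were fixed before the data were examined. Those for the noncoding table held 7SL, 7SK, RNase P and MRP, major snRNAs, U6, minor snRNAs, U7, the snoRNAs U3, U8 and U13, C/D box and H/ACA box snoRNAs, scaRNAs, Y RNAs, vault RNAs, 5S rRNA, other rRNA, let-7, other miRNA genes, mitochondrial tRNA and rRNA, and lncRNAs. Those for the mRNA table held Dis3l2 with uridylation enzymes, other RNA decay factors, replication histones, ribosomal proteins, mitochondria-encoded genes, ER chaperones with secretory genes, pluripotency genes, endoderm, mesoderm, ectoderm, trophectoderm and fibroblast markers, interferon response, immediate early and stress genes, and housekeeping genes. For lists with at least 3 measured members, the list's median was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was said to stand apart below the 2.5th or above the 97.5th percentile, as a description of these libraries. The name pattern for major snRNAs also took Rnu11 and Rnu12, which belong to the minor spliceosome, and U8 and U13 are also in the C/D box list.

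Genes were named by a rule fixed before the data were examined. It took Dis3l2; per table, the 10 highest and 5 lowest for the specific enrichment and for mutant IP over mock IP; the 5 highest and 5 lowest between inputs; the 3 highest for IP over input; and up to 4 members of each list by mean level. Features had to reach 5 in the library concerned. Names chosen after their values were seen are marked so.

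The mRNA table held 307324 reads for the mutant input, 291175 for the mock input, 2275647 for the mutant IP and 1860030 for the mock IP. The noncoding table held 2746737, 2738512, 3183346 and 2157604 reads in the same order. The ratios were tested on simulated reads for mutant IP against mock IP, with 50 features changed per direction and size in each table. Of features raised 16-fold, 45 were recovered in the noncoding table and 49 in the mRNA table, and of those raised 8-fold, 33 and 43. Of features lowered 16-fold, 47 and 50 were recovered, and of those lowered 8-fold, 38 and 45. Of unchanged features, 1 of 3135 and 4 of 13711 passed 4-fold. The intervals held the true fold for 95.8% and 96.8% of 500 features. Simulated reads varied by counting error only. Features of the real IPs with at least 10 reads were also grouped by depth. In these groups 43.5% to 61.0% lay outside counting error around the group median. The simulated rates therefore hold for counting error only and not for the real libraries. Of 200 random lists in the mRNA table, 9 lay outside the percentile range.

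Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, a minimum of 5 or none, libraries centred on the median of features with at least 1 in all libraries, libraries scaled to the same total, and all transcripts instead of 1 per symbol. Added after seeing the data were a minimum of 20 reads per library on average, a count of ratios whose whole interval lay beyond the threshold, the snRNA list without Rnu11 and Rnu12, and the miRNA list without host genes. A genome of the build used was not used here, so repeats and sequence similarity were not examined. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.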

Results

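The series set out to find RNAs bound by mutant Dis3l2 in mouse embryonic stem cells. It holds 4 libraries, 1 each of mutant input, mock input, mutant IP and mock IP. The mock IP measures what the anti-FLAG gel recovers from cells without the tagged protein and is the background for the mutant IP. Inputs were selected against ribosomal RNA and the IP RNA was not described as selected, so a ratio of IP to input also compares RNA prepared in different ways. The mRNA table was shallow in the inputs, with 307324 and 291175 reads for mutant and mock against 2275647 and 1860030 in the IPs. A large share of its reads was assigned to 1 gene, Lars2, a mitochondrial leucyl-tRNA synthetase. Lars2 held 33.3% of the mutant input (exact 95% interval 33.1 to 33.5), 34.8% of the mock input, 52.0% of the mutant IP and 58.6% of the mock IP. Whether these reads come from Lars2 mRNA or from similar sequence elsewhere was not examined. In the noncoding table Rn18s-rs5, an 18S ribosomal RNA, held 10.4%, 12.1%, 37.1% and 42.4% of 2746737, 2738512, 3183346 and 2157604 reads in the same order. Another 21 transcripts with counts within 20% of the U1 snRNA Rnu1a1 held 53.7%, 53.4%, 9.42% and 1.66% of the noncoding total.

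Dis3l2 itself had 127 reads in the mutant IP and 21 in the mock IP, a ratio of 5.60 (95% interval 3.51 to 9.36). The inputs held 7 reads in the mutant and 3 in the mock, a ratio of 3.24 whose interval ran from 0.740 to 19.4. A higher Dis3l2 level in the mutant input was therefore not detectable at this depth. Its specific enrichment was 1.20 on the log2 scale, under the 4-fold threshold. Whether these reads come from the cells' own transcript or from the transfected construct is not given in the sources used here.

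Mutant IP was set against mock IP to find RNAs that depend on the tagged protein. Among noncoding RNAs the 7SL RNAs, the RNA of the signal recognition particle, were far higher in the mutant IP: Rn7s1 had 45304 reads in the mutant IP and 890 in the mock IP, a ratio of 47.1 (95% interval 44.1 to 50.4), and Rn7s2 and Rn7s6 gave 49.5 and 46.2. The RNAs of RNase MRP, which processes ribosomal RNA, and of RNase P, which trims tRNA precursors, rose by 19.5-fold for Rmrp (17.4 to 21.8) and 7.43-fold for Rpph1 (6.75 to 8.19). U1, the snRNA that recognises 5′ splice sites, rose by 8.01-fold for Rnu1a1 (7.62 to 8.41). The 5S ribosomal RNA copies had a median log2 ratio of 2.19, and 43 of 59 measured copies passed 4-fold while 0 were lower. In all, 475 of 3506 noncoding features were at least 4-fold higher and 210 lower, with a median log2 ratio over all features of 0.47. With libraries centred on the median these counts were 339 and 281, and with equal totals 395 and 329.

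All 3 measured 7SL RNAs passed the threshold, with a median of 5.55 at the 99.9th percentile of matched random lists. Both RNase P and MRP RNAs passed it, with a median of 3.58. Of 8 snRNAs taken by the list of major snRNAs, 5 rose and 0 fell, with a median of 2.88 at the 99.6th percentile. The 5 that rose were U1 and U2 RNAs. Rnu1b1, Rnu1b2 and Rnu1b6 gave 7.43-, 7.33- and 7.41-fold, and Rnu2-10, a U2 snRNA chosen after its values were seen, 10.4-fold (8.96 to 12). The U11 and U12 snRNAs of the minor spliceosome stayed below the threshold, at 2.83-fold for Rnu11 (1.90 to 4.34) and 2.51-fold for Rnu12 (1.89 to 3.36), with a list median of 1.37. The 5S list lay at the 100th percentile, and its most abundant copies n-R5s103 and n-R5s146 rose 5-fold (4.25 to 5.90) and 5.04-fold (4.26 to 5.99). Copies of 7SL, U1 or 5S are not independent, while the random lists were drawn from features in general. The percentiles of the 7SL, major snRNA and 5S lists, here and below, therefore count 1 RNA more than once. After centring, the 5S median was 1.74, below 4-fold, while the medians of 7SL and the major snRNAs were 5.09 and 2.42.

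Several small RNAs seen almost only in the mutant IP were also higher. The Y RNAs, partners of the Ro60 protein, had 57 reads for Rny1 and 19 for Rny3 against 0 in the mock IP, at least 17.6- and 5.87-fold higher. The vault RNA Vaultrc5 rose 22.4-fold (12 to 47.3), from 10 to 242 reads. Snord118, the U8 snoRNA needed for ribosomal RNA processing, had 141 reads against 0, at least 43.5-fold higher, whereas Snord13 had 29 against 8, a ratio of 3.36 (1.5 to 8.5), so that 1 of the 2 measured RNAs of the U3, U8 and U13 list rose.

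The medians of the C/D and H/ACA box snoRNAs depended on the settings, and 7SK and the mitochondrial RNAs stayed below 4-fold. Of 17 C/D box snoRNAs, 4 rose and 3 fell, with a median of -0.16 at the 16.4th percentile; with a minimum value of 5 only 7 were left, and their median of 1.48 lay at the 97.9th percentile. Of 18 H/ACA box snoRNAs, 1 rose and 2 fell; their median of 0.86 at the 99.1st percentile became 0.33 at the 38.7th with a pseudocount of 5, and 0.51 at the 67.8th with a minimum value of 5. The abundant H/ACA RNA Snora64 had 12 reads in the mutant IP and 13 in the mock IP. Of 5 scaRNAs, which guide snRNA modification, 1 rose and 1 fell around a median of 0.55 at the 59.9th percentile; Scarna13 had 38 reads against 2, a ratio of 17.6 (4.55 to 151). Rn7sk, the 7SK RNA that restrains transcription elongation, gave 1.39-fold (1.27 to 1.52). Of 22 lncRNAs 0 rose and 1 fell, with a median of 0.33 at the 20.6th percentile, and Malat1 gave 1.28-fold (1.26 to 1.30), which turned to a log2 ratio of -0.10 after centring. Of 54 other miRNA genes 9 rose and 2 fell, with a median of 0.71 at the 63.8th percentile. None of 4 mitochondrial rRNAs and tRNAs passed the threshold, with a median of 0.91 at the 72.3rd percentile. Rn18s-rs5, the only member of the list of other rRNA, gave 0.26, which turned to -0.21 after centring. U6 and let-7 had 0 measured members, and the name pattern for U7 matched 0 rows.

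The 10 noncoding features with the highest ratio included Rn7s1, Rn7s2, Snord118 and clone-named or predicted RNAs. Gm26461 had 949 reads in the mutant IP and 7 in the mock IP, a ratio of 126 (60.7 to 313), and Gm25202 had 323 and 1, a ratio with an interval from 53.3 to 11849. AC157822.1, AC099934.1 and AC156953.1 gave 63.4, 61.2 and 58.7, and Gm25813 gave 73.6 (37.1 to 171). 2900060B14Rik had 203 reads against 0, at least 62.7-fold higher. The lowest were 1810008B01Rik, Gm20400 and Gm26802, with 37, 36 and 36 reads in the mock IP and 0 in the mutant IP, and 2610020C07Rik with 29 and 0, which are at least 13.3-, 13-, 13- and 10.4-fold lower. Gm42864 had 36 mock reads and 1 mutant read.

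**Figure D1:**
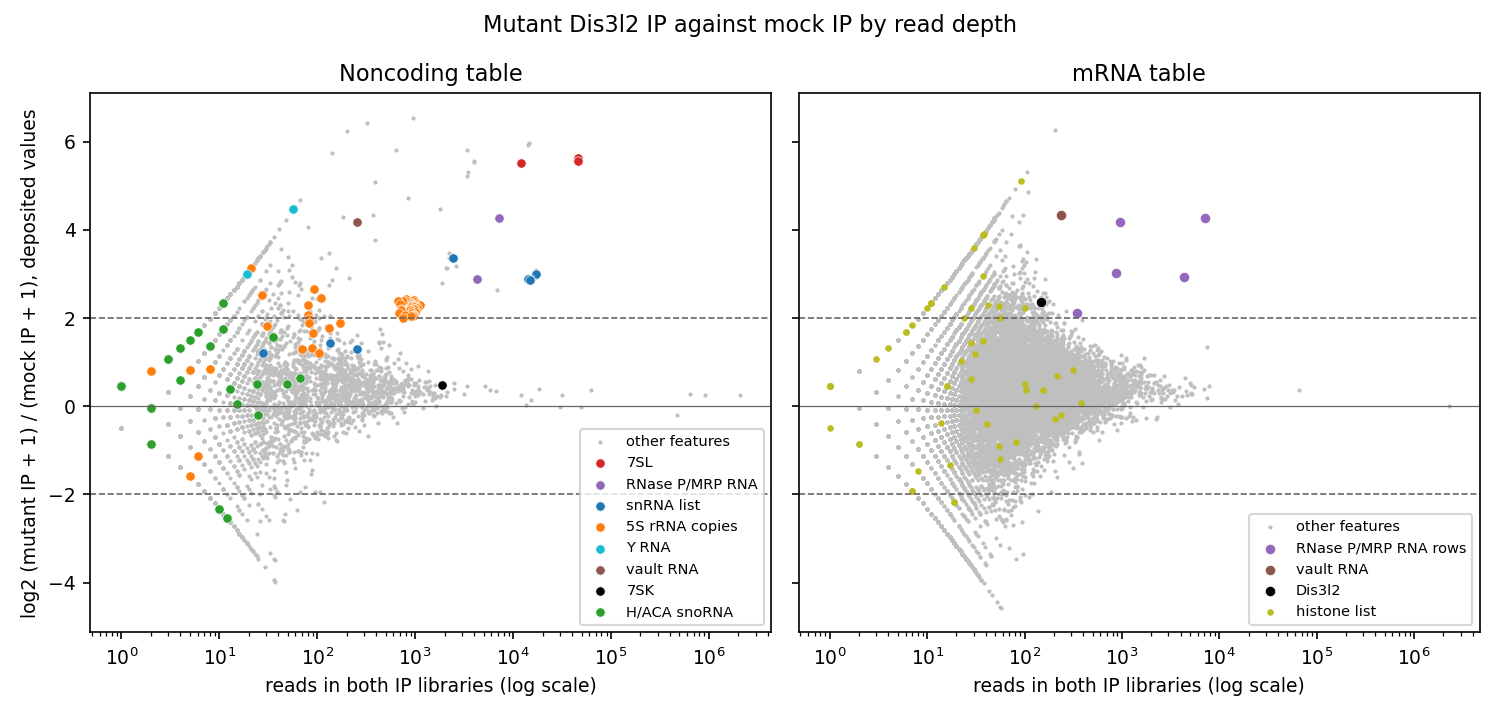
Each point is 1 feature of the noncoding table (left) or the mRNA table (right), placed by its reads in both IP libraries (log scale) and its log2 ratio of mutant IP over mock IP with a pseudocount of 1; colours mark the named RNA classes and dashed lines mark 4-fold. Among features with at least 300 reads, 97 of 419 noncoding and 5 of 1291 mRNA-table features lie above the upper line and 0 below the lower one, while at 10 to 19 reads points fill both sides. The 97 include copies of U1 and of 5S RNA, which are not independent observations. How many separate RNAs the 97 stand for was not counted.

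In the mRNA table, reads of Dis3l2, whether from the cells or the construct, and of the terminal uridylyltransferase Zcchc11 (Tut4) were higher in the mutant IP, whereas pluripotency, housekeeping, ribosomal protein and endoderm genes had medians close to that of all features, 0.38. Zcchc11, with 16 reads in the mock IP, gave a ratio of 8.45 (5.03 to 15.2), while Zcchc6, Lin28a and Papd5 gave 1.02, 1.38 and 1.06. Of the 10 members of that list 3 rose and 0 fell, with a median of 0.35 at the 44.4th percentile, which became 0.97 at the 95.2nd for the 8 members left with a minimum value of 5. In all, 1436 of 14273 features were at least 4-fold higher and 819 lower. With libraries centred on the median the counts were 298 and 294, and with equal totals 688 and 459. Centring itself draws the counts of higher and lower features together. Centring moved the median of all features between the IPs to 0.01 here and to 0.06 in the noncoding table, and turned the medians of other RNA decay factors, lncRNAs, pluripotency and housekeeping genes below 0, to -0.33, -0.12, -0.03 and -0.12. At 10 to 19 reads 595 of 1934 features were higher and 373 lower, but at 300 reads or more 5 of 1291 were higher and 0 lower. These 5 were Rmrp, Rpph1 and the RNase P-like RNAs Rprl1, Rprl2 and Rprl3, chosen after their values were seen.

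Replication histones stood apart, with 16 of 51 measured genes higher, 2 lower and a median of 1.03 at the 99.8th percentile; Hist1h3f had 91 reads against 0, at least 28.1-fold higher. The 4 most abundant histone genes stayed below 4-fold, with Hist4h4 at 1.79-fold (1.41 to 2.29) and Hist1h1c at 0.873 (0.671 to 1.14), and with a minimum value of 5 the median was 0.76 at the 90.6th percentile. Other RNA decay factors had the lowest median among the lists of the mRNA table, 0.03 at the 4.29th percentile, with 1 of 25 higher and 0 lower. Cnot1, a scaffold of deadenylation, gave 1.09 (0.970 to 1.23). Of 82 ribosomal protein genes 2 rose and 2 fell (median 0.43, 81.9th percentile), and of 26 ER chaperone and secretory genes 2 rose and 0 fell (0.52, 87.7th). All 24 pluripotency genes stayed within 4-fold (0.25, 22.8th), with Zfp42 (Rex1) at 1.45-fold (1.28 to 1.64) and Tdgf1 at 1.38-fold (1.26 to 1.52).

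Of endoderm markers 3 of 11 were higher and 2 lower (median 0.42, 59.4th percentile), of mesoderm markers 2 of 5 and 1 (0.59, 50.4th), of ectoderm markers 1 of 8 and 1 (0.76, 79.5th), and of trophectoderm markers 0 of 6 and 0 (0.96, 80.1st). Among fibroblast markers, 1 of 6 was higher and 0 lower (1.14, 91.0th). Interferon response genes had 1 of 11 higher and 1 lower (1.53, 95.2nd). Immediate early and stress genes had 1 of 12 higher and 0 lower (0.76, 90.2nd), and housekeeping genes 2 of 12 and 0 (0.25, 29.1st), with Eef2 at 1.21-fold (1.15 to 1.28). Mitochondria-encoded genes matched 0 rows.

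The highest single genes rested on few mock reads. Vps33a, a subunit of vesicle tethering complexes, had 105 reads against 0, at least 32.4-fold higher. Casz1, Muc5b, Unc93b1, Zfp748, Ccnyl1 and 1700123O12Rik had 0 mock reads and were at least 24.4-, 21.3-, 20.1-, 20.1-, 19.1- and 18.5-fold higher. H2-Q5 had 107 reads against 1, a ratio of 99.1 (17.4 to 3949), and 2900060B14Rik 205 against 0, at least 63.3-fold higher. The lowest genes had 0 mutant reads: Morc1, with 57 mock reads, was the lowest, and Ece2, Lancl1, Ndst2 and Nnt were at least 20.2-, 18.7-, 16.6- and 15.5-fold lower.

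The specific IP enrichment also accounts for the inputs, and it again set the lists of 7SL, major snRNAs and 5S RNA apart, but not the H/ACA box snoRNAs. The 7SL RNAs had a median log2 value of 5.19 at the 99.9th percentile, with 5.13 for Rn7s1, 5.19 for Rn7s2 and 5.20 for Rn7s6. Rmrp reached 4.03, Rpph1 2.52, Rnu1a1 2.53 and Rnu2-10 3.05. The 5S copies had a median of 3.85 at the 100th percentile with 52 of 59 higher and 0 lower, larger than between the IPs because the same copies were lower in the mutant input. Over all noncoding features 526 of 3968 were at least 4-fold higher and 345 lower, with a median of 0.03.

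Of the major snRNA list 5 of 8 rose and 0 fell (median 2.38, 99.1st percentile), and both Y RNAs and the vault RNA rose, with 3.12 for Vaultrc5. For the Y RNAs, with 0 members measured between the inputs, the median of 3.74 is the same as between the IPs. Their specific enrichment therefore adds no separate observation. Snord118 rose, at 5.18. Of 20 C/D box snoRNAs 4 rose and 4 fell (-0.69, 15.3rd percentile; 1.48 at the 96.8th for the 7 with a minimum value of 5), of 37 H/ACA box snoRNAs 0 rose and 4 fell (-0.19, 23.2nd), and of 8 scaRNAs 1 rose and 2 fell (-0.23, 29.5th; 0.25 at the 73.7th for the 7 with a minimum value of 5). The minor snRNAs had 1.03 for Rnu11 and -0.01 for Rnu12. Rn7sk gave -0.17, the lncRNA list a median of -0.10 with 0 of 22 higher and 1 lower, and Rn18s-rs5 0.00. The highest features were Gm26461 at 6.47, 2900060B14Rik at 6.25, Gm42941 at 5.83, AC156953.1 at 5.57, Gm25813 at 5.48, Gm12500 at 5.40, Gm26751 at 5.31, Gm37864 and AC157822.1 at 5.30 and AC099934.1 at 5.27. The lowest were Gm28262 at -6.33, 2610020C07Rik at -5.77, Gm10538 at -5.58, Gm20400 at -5.36 and Gm42849 at -4.80, each with 0 reads in the mock input.

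In the mRNA table, 2079 of 15060 features were at least 4-fold higher in the specific ratio and 1593 lower, with a median of 0.13; centring turned the counts to 1931 and 2116 and the median to -0.09, and in the noncoding table the counts to 448 and 420 and the median to -0.18. Zcchc11 reached 3.13 and its list had 3 of 10 higher and 1 lower, with a median of 1.21 at the 96.7th percentile. Replication histones had 17 of 53 higher and 3 lower (0.88, 98.6th percentile) and stood apart only in the main setting, not under any of the 4 alternatives run for this list. Ribosomal proteins lay at the 97.49th percentile, just within the range, with a median of 0.25, 5 of 82 higher and 7 lower. Of other RNA decay factors 2 of 25 rose and 3 fell (-0.09, 31.7th), and of pluripotency genes 2 of 24 rose and 0 fell (-0.04, 50.4th). The highest genes had few input reads: Gm20125 at 7.09, Muc5b at 7.05, Gm6602 at 6.16, Fzd10 at 6.08, Iscu at 5.57, Casz1 at 5.55, 4833417C18Rik at 5.52, Enthd2 at 5.51, Cox7a2l at 5.45 and Eme2 at 5.43 had 0 to 4 reads in the mutant input. The lowest, Agtpbp1 at -6.34, Pik3c3 at -6.18, Dph1 at -5.85, Hras1 at -5.82 and Fam189b at -5.80, had 0 reads in the mock input.

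IP over input was compared within each condition to see what the gel retained. Selection of the inputs against ribosomal RNA may also enter these ratios. In the mutant, 7SL, RNase MRP and 5S RNA were above or near their input level, and in the mock 7SL and RNase MRP were far below it: Rn7s1 was at 1.8 times its input in the mutant (1.77 to 1.83) and at 0.0513 times in the mock (0.0479 to 0.0548). Rmrp was at 1.82 and 0.111 times, Rnu1a1 at 0.141 and 0.0244, and n-R5s103 at 14.8 and 0.922. H/ACA box snoRNAs were far below input in both conditions, with medians of -5.64 in the mutant and -6.27 in the mock on the log2 scale; 32 of 36 and 28 of 34 fell by at least 4-fold, and Snora64 was at 0.00125 and 0.00189 times its input. Malat1, a nuclear lncRNA, was at 18.9 and 20.3 times its input here, and its transcript in the mRNA table at 32.0 times (29.8 to 34.4) and 33.7 times (31.4 to 36.2).

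In the noncoding table, 877 of 3406 features rose and 351 fell in the mutant, and 736 of 3138 rose and 336 fell in the mock, with medians of 0.90 and 0.79. Deeper features went the other way: among those with at least 20 reads in each library, the medians were -0.42 in the mutant and -0.34 in the mock. Gm15564 and Mir6240, at 169 and 81.2 times input in the mutant and 90.1 and 51.1 in the mock, were among the highest in both conditions, with 2900060B14Rik (203 reads against 0) in the mutant and Gm26853 (244 reads against 0, at least 81.3-fold) in the mock. In the mRNA table, 8330 of 13637 features rose and 316 fell in the mutant, and 7940 of 13111 rose and 252 fell in the mock. Centred, these counts were 2921 and 1302 in the mutant and 3140 and 1309 in the mock, and with equal totals 4028 and 1429, and 3678 and 1513. ER chaperone and secretory genes had medians of 3.42 and 3.32, at the 99.3rd and 99.6th percentiles, with 23 of 25 and 20 of 26 higher. Pluripotency genes had 3.25 and 3.14, at the 97.3rd and 97.9th percentiles, and housekeeping genes 3.25 and 2.92, at the 97.6th and 75.8th. Ribosomal protein genes stood apart low only in the mock, at 2.14 and the 0.63rd percentile, against 2.46 and the 20.3rd in the mutant. By the ratio with a pseudocount of 1, the highest genes in the mutant were Zfp57, Ddx5 and Trap1a. They stood at least 154-, 101- and 88.2-fold above inputs of 0 reads. In the mock the highest by that ratio were Mdm4, Plekhm1 and Zkscan1, at least 160-, 94.3- and 94.3-fold above input.

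**Figure D2:**
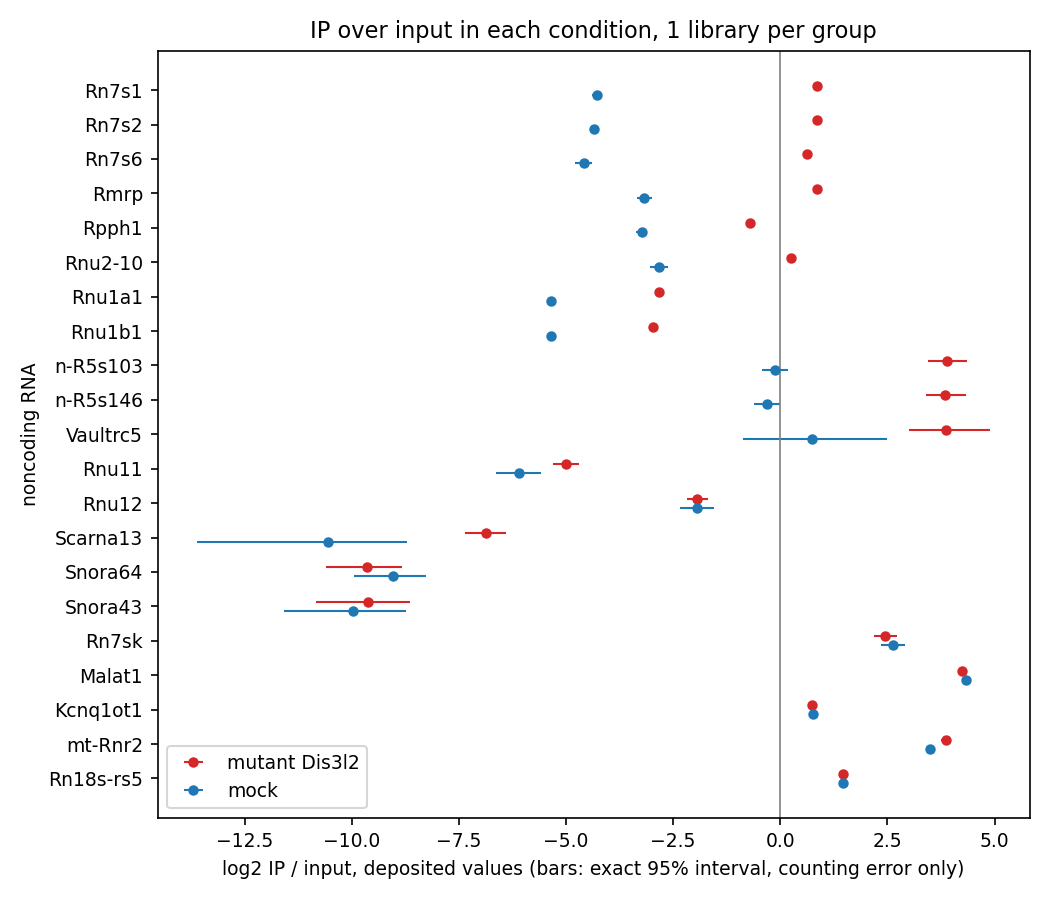
Log2 ratio of IP to input, on deposited values without a pseudocount, for 21 noncoding RNAs in the mutant (red) and mock (blue) libraries, 1 library per group, with bars for exact 95% intervals of counting error. Rn7s1 lies at 1.8 times its input in the mutant and 0.0513 times in the mock, whereas Malat1, at 18.9 and 20.3 times, and Snora64, at 0.00125 and 0.00189 times, have similar values in both conditions.

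The inputs were compared to see whether RNA levels differed between the transfections. The 5S copies were lower in the mutant input, with 48 of 50 measured copies at least 2-fold lower, 0 higher and a median log2 ratio of -1.77 below all 10000 random lists; n-R5s103 had 43 reads against 192, a ratio of 0.311 (0.218 to 0.435), and n-R5s146 41 against 203, a ratio of 0.281 (0.195 to 0.394). Gm26870 was higher, with 78364 reads against 8278, a ratio of 13.1 (12.9 to 13.5), while the IPs held 67 and 56 of its reads. 7SL, RNase P and MRP, and U1 stayed within 2-fold, at 1.34 for Rn7s1, 1.19 for Rmrp, 1.29 for Rpph1 and 1.39 for Rnu1a1. In all 735 of 2533 noncoding features were at least 2-fold higher and 344 lower (median 0.48), which became 422 and 415 with equal totals.

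Housekeeping genes had 1 of 9 higher and 2 lower between inputs (median -0.04, 3.72nd percentile), ribosomal proteins 18 of 77 and 8 (0.29, 13.6th), ER genes 8 of 21 and 4 (0.54, 68.5th) and pluripotency genes 3 of 19 and 3 (0.41, 45.0th). In the mRNA table, 3463 of 9367 features were higher and 2038 lower (median 0.51), which became 3131 and 2803 with equal totals. The highest were Fadd, an adaptor of death receptors, with 44 reads against 1, a ratio of 61.1 (10.4 to 2468), and AU023762, Heatr3, Gnb1l and Edc4, at least 12.5-, 12-, 11.6- and 10.7-fold higher against 0 reads. The lowest were Heatr5a, Nob1, Mfap1b, Cdc5l and Slc35d2, with 0 reads in the mutant input and at least 8.88-, 6.96-, 6.96-, 6.72- and 6.48-fold lower. Among noncoding features Gm28262, Gm26853, Gm15883 and Gm12018 were at least 18.1-, 8.80-, 8.80- and 7.87-fold higher against 0 reads, and 4930448E22Rik was at least 4.8-fold lower. Appbp2os, AC124193.1, Gm17514 and Gm29129 had 1, 2, 0 and 0 reads in the mutant input against 19, 24, 14 and 13.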

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

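All explanation tests of this part were chosen, and some later revised, only after the results were seen. The RNAs listed first come from the gene lists and from the highest of the specific enrichment and of mutant IP over mock IP; they were picked out because the counting interval of IP over input lay wholly above 1 in the mutant and wholly below 1 in the mock, and with 1 library per group this difference was not tested. The patterns weighed after them were chosen after their values were seen, and not all of their RNAs meet that rule.

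Among noncoding RNAs the specific enrichment of these was 5.13 for Rn7s1, 5.19 for Rn7s2, 5.20 for Rn7s6, 4.03 for Rmrp, 4.10 for the 5S copy n-R5s146, 5.30 for AC157822.1, 5.27 for AC099934.1, 5.48 for Gm25813, 5.31 for Gm26751 and 5.83 for Gm42941 on the log2 scale. In the mRNA table it was 5.55 for Casz1, 7.05 for Muc5b, 6.08 for Fzd10, 6.16 for Gm6602, 5.57 for Iscu, 7.09 for Gm20125, 5.43 for Eme2 and 5.51 for Enthd2. Of these 8 genes, 7 had 0 reads in the mutant input and Casz1 had 4.

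The 7SL, RNase MRP and P, U1, U2 and 5S RNAs were higher in the mutant IP than in the mock IP. A difference in scaling would have moved other deep features alike, but the median log2 ratio of mRNA-table features with at least 300 IP reads was 0.374. Carry-over of input RNA would have needed 11.1% (Rnu1b1) to 178% (Rn7s2) of the mutant input for 7SL, RNase MRP and P, U1 and U2. The most retained abundant H/ACA box snoRNA, Snora73b, stood at 1.28%. This bounds only a carry-over that is alike for all RNAs, since H/ACA box snoRNAs were far below input in both IPs. Carry-over particular to 7SL, RNase MRP and P, U1 or U2 was not tested. For the 5S copies the median needed was 1183%, but of an input that had been selected against ribosomal RNA. That value therefore cannot bound carry-over of unselected 5S RNA. Uneven reads at single features were weighed with the 1291 mRNA-table features with at least 300 IP reads, RNase P and MRP RNA included. Their absolute log2 ratios had a 99th percentile of 1.43, below the 5S median of 2.19, although the 5S copies are not independent of each other. Ratios of this size were thus rare among deep mRNA-table features. Most measured features of that table, 12559 of 14273, are protein-coding, so their spread may not hold for short RNAs and does not settle the question. Noncoding features of that depth reached a 95th percentile of 3.40, but they include the RNAs weighed here and give no separate reference. Binding to the tagged mutant protein is a hypothesis that may account for the pattern, but other differences between 2 single preparations stay open.

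The 5S copies were lower in the mutant input than in the mock input. Stronger depletion of all ribosomal RNAs is argued against by Rn18s-rs5, which lay at -0.175 relative to the median of the deeper noncoding features, and mt-Rnr2 at -0.55, against -2.20 for 5S; mt-Rnr1, at -1.13, was lower than either, and 7 features of class rRNA outside the 5S list were at least 2-fold lower too. Uneven counts were weighed with all 355 mRNA-table features with at least 100 and under 300 input reads. Their log2 ratios had a 1st percentile of -0.600 against a 5S median of -1.77, both not relative to the median. The 5S copies are not independent of each other, however. Most measured features of the mRNA table, 8275 of 9367 between the inputs, are protein-coding, so their spread may not hold for short RNAs and does not settle the question. Noncoding features of that depth had a 5th percentile of -1.79. Of the 46 at least 2-fold lower there, 44 were in the 5S list or class rRNA, so they give no separate reference. A depletion difference particular to 5S or to some rRNAs, and an effect of the transfected protein, were not tested and stay open.

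Gm26870 was 12.8- to 13.1-fold higher in the mutant input over its 3 transcripts, and took 5.97% of the noncoding total against 0.642% in the mock input. Genomic DNA in that library stays open: chemosensory receptor genes with few mock reads, at 179 against 145 reads in sum, had a ratio of 1.71 (95% interval 1.37 to 2.15), slightly above the general ratio of 1.35 between the inputs. The receptor genes with at least 100 mock reads were left out of that sum and rose more, at 2.55 for Olfr613, 3.57 for Olfr856-ps1 and 2.01 for Vmn1r58. A difference in scaling is argued against by the median log2 ratio of 0.430 over noncoding features with at least 20 reads in each input, and their 95th percentile of 1.24. Reads shared with repeats elsewhere in the genome were not tested, and a biological difference between the transfections stays open.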

How the results depend on the processing

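Most counts of features past a threshold moved by more than 1.5 times with other pseudocounts, with at least 20 reads per library on average and with the exact interval, as did 10 of 20 with a minimum of 5, 8 with equal totals and 6 with centring, so they describe these settings and not a number of bound RNAs. With no filter on low values and with all transcripts kept, all 20 counts stayed within 1.5 times. A pseudocount of 5 shrinks and one of 0.1 widens the ratios of features with few reads by construction; for the other settings the cause was not tested. No paired analysis was possible because each group has 1 library and no sample number links them. The intervals cover counting error only.

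Counts below are higher and lower features, and a count not given stayed within 1.5 times of the main one. With a pseudocount of 0.1, the specific enrichment gave 1068 and 912 in the noncoding and 3981 and 3744 in the mRNA table, and mutant against mock IP 888 and 525, and 2465 and 1564. IP against input gave 1432 and 602 noncoding features and 851 lower mRNA-table features in the mutant, and 1287 and 553, and 769 lower, in the mock. With a pseudocount of 5, the specific enrichment gave 137 and 13, and 206 and 84, and mutant against mock IP 110 and 0, and 90 and 10. IP against input gave 211 and 224, and 3853 and 86, in the mutant, and 101 and 232, and 3105 and 79, in the mock, so that more noncoding features fell than rose in both conditions. The inputs gave 169 and 58, and 742 and 174.

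Among features with at least 5 in any library used, the specific enrichment gave 350 and 158 noncoding features, and mutant against mock IP 76 lower noncoding and 441 lower mRNA-table features. IP against input gave 209 lower mRNA-table features in the mutant and 485 higher noncoding features in the mock, and the inputs 290 and 86, and 1309 and 365.

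With each library centred on the median, mRNA-table counts were 298 and 294 for mutant against mock IP, 2921 and 1302 for IP against input in the mutant, and 3140 and 1309 in the mock. With each library scaled to the same total they were 688 and 459, 4028 and 1429, and 3678 and 1513; among noncoding features 329 were lower in the mutant IP and 422 higher in the mutant input.

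The next settings were chosen after seeing the data. With at least 20 reads per library on average, the specific enrichment gave 150 and 32 noncoding and 580 and 399 mRNA-table features, and mutant against mock IP 157 and 6, and 344 and 62. IP against input gave 278 and 247, and 4933 and 96, in the mutant, and 162 and 253, and 4032 and 101, in the mock, where the majority of noncoding features past the threshold turned to lower. The inputs gave 152 and 52, and 287 and 54. Counting only ratios whose whole exact interval lay beyond the threshold, mutant against mock IP gave 161 and 36, and 414 and 209. IP against input gave 292 and 233, and 4779 and 124, in the mutant, and 262 and 246, and 4867 and 105, in the mock. The inputs gave 114 and 47, and 758 and 149. Leaving Rnu11 and Rnu12 out of the snRNA list, or host genes out of the miRNA list, changed no call.

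Among gene lists, the C/D box snoRNAs changed sides between the IPs, to a median of 1.48 with a minimum of 5, and the H/ACA box snoRNAs changed sides, to 0.33, with a pseudocount of 5 and left the outer range, at 0.51, with a minimum of 5. Replication histones left it for the specific enrichment with pseudocounts of 0.1 (0.85) and 5 (0.43), a minimum of 5 (0.72) and centring (0.53), and between the IPs with a minimum of 5 (0.76). With a minimum of 5, lists that entered it were ribosomal proteins for the specific enrichment (0.26) and between inputs (0.26), and between inputs ER genes (0.95) and housekeeping genes (0.0347). Of 272 list values under an alternative, another 18 stayed inside the range but moved to the other side of the random median, among them the specific enrichment of C/D box snoRNAs (15.3rd to 96.8th percentile) and scaRNAs (29.5th to 73.7th) with a minimum of 5 and of H/ACA box snoRNAs (23.2nd to 71.9th) with centring. The 7SL, major snRNA and 5S lists stayed above the range between the IPs and for the specific enrichment.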

Other observations

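The classes in this part come from a RefSeq gene table and were set beside the ratios only after the results were seen. By those classes, 36 of 67 measured snRNAs in the noncoding table were at least 4-fold higher in the mutant IP than in the mock IP and 1 was lower, with a median log2 ratio of 2.59. Copies of 1 snRNA are not independent, and 21 noncoding transcripts had counts within 20% of the U1 snRNA Rnu1a1. How many separate RNAs these snRNAs stand for was not counted. Of 56 features of class rRNA, which was not separated from the 5S list, 46 were higher and 0 lower, with a median of 2.21. The 5S list alone had 43 of 59 higher and a median of 2.19, while Rn18s-rs5 gave 0.26. The class is therefore no separate observation on ribosomal RNA in general. Guide RNAs had a median of 1.5, with 3 of 13 higher and 1 lower. Of 62 snoRNAs 8 were higher and 9 lower, with a median of 0.62, and their medians for IP over input were -4.23 in the mutant and -3.30 in the mock. Of 1239 lncRNAs 136 were higher and 82 lower, with a median of 0.41, close to the 0.47 of all noncoding features.

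Rn4.5s, a short rodent RNA, had 5540 reads in the mutant IP and 2016 in the mock IP, a ratio of 2.54 (95% interval 2.42 to 2.68) that stayed under 4-fold, and its specific enrichment was 1.57. Terc, the telomerase RNA, had 13 and 6 reads, a ratio of 2.01 (0.711 to 6.44). Both were chosen after their values were seen. Several genes with many input reads were also higher in the mutant input, chosen in the same way: Zfp781 gave 4.71-fold, the olfactory receptor pseudogene Olfr856-ps1 3.57-fold, Zfp488 3.08-fold, Gm17821 2.80-fold, the mRNA-table transcript of Kcnq1ot1 2.75-fold, Olfr613 2.55-fold and Vmn1r58 2.01-fold, while their mutant to mock ratios between the IPs lay between 0.963 for Zfp781 and 1.31 for Gm17821.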
